A study of soil metagenome with 27 samples.

How the data were processed

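DNA from 27 soil samples, 9 from each of the forests SWD, BDGS and HH, was hybridized to GeoChip arrays, and 15 soil and vegetation variables were recorded for the same 27 plots. Per the labels, soil DNA was extracted with the PowerMax kit and labelled by random priming. The label field names Cy3 and the labelling protocol names Cy-5, so the dye is not settled here. The scanner, the image software, hybridization batches and the rule by which spots were called present are not given in the sources used here. Samples were grouped by the forest named in their titles, and each title was matched to its column of the tables through the column name given in its description. Arrays and plots are numbered here by the replicate number of the title, which for HH and part of SWD is not the number in the column name.

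The raw table holds the intensity of each probe as deposited, with a blank where no value was kept (38901 probes, 6059 without a value in any array). The normalized table holds the natural log of scaled intensity, as the deposited values show: ln(x + 1), where x is the raw intensity times a single factor for each array. The factor made the kept probes of every array sum to 163.3 in units of 1000000, and a 0 stands where the raw value is blank (2.70% of values). The unit was settled from the values, since the file does not state it. The probes kept by the authors are exactly the 23820 with a raw value in at least 4 of 9 arrays of every forest, 61.2% of the raw table, and 9022 probes with some value were left out. A second deposited sheet holds another unit, sums of the natural log values over the probes of each of 345 genes; it equals the sums of the probe table and was used only as an alternative. The deposited environmental table gives other variables with column names and no units; the meaning of dIVI is not given, and its values are not reported here.

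Normalized values were taken back to linear intensity (exp of the value minus 1). A gene family's value in an array was the log2 of its summed linear signal over detected probes, and a family was tested if at least 3 of its probes were detected in at least 5 of 9 arrays of a forest (286 families). A probe was tested in a comparison if detected in at least 3 arrays of each forest, undetected values being missing. Families and probes were compared in limma 3.58.1 (R 4.3.3) with a mean per forest, all 27 arrays in the fit, two-sided tests, and Benjamini-Hochberg adjustment within a comparison at 0.05. Detected probes, the Shannon index (natural log, over the ln values), shares of domains and soil variables were compared by two-sided exact permutation tests over all 48620 splits of 9 against 9. Functional structure was tested by PERMANOVA (adonis2) on Bray-Curtis distance over the ln values with vegan 2.7.1, and within forests by the variable after forest with permutations within forests. Lists were tested with limma's camera (preset correlation 0.01). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.

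The comparisons, the 15 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, in each comparison, the 6 families with the largest positive and the 6 with the largest negative difference among those past the threshold with at least 5 probes detected in 5 or more arrays of a forest. It added up to 2 members of each list with the smallest adjusted p, and the 2 highest and 2 lowest probes among those past the threshold and detected in all 18 arrays. List names were matched to the array's gene names without regard to case, and 13 lists had measured members. A named probe is given by its gene and its annotated source organism, without the strain.

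Alternatives tried were the mean signal per probe, the mean log2 over probes detected in all arrays, quantile normalization, division by the array total, other filters, a floor for undetected probes, the raw table, the replicate number as a block, fits to 2 forests, array weights, other distances, ranks and logs of the variables, and each array left out in turn. After seeing the data, centring on the median of the shared probes, the log2 of the summed ln values, linear values for the Shannon index and for Bray-Curtis distance, leaving out BDGS arrays 2, 3 and 4, and a methane list without mdh were added. Of the lists, quantile normalization and shared-probe means were also added then.

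The methods were tested on simulated data of the same size. Of 60 of 286 families changed by log2 0.1 or 0.2, 63.3% and 80.0% were recovered for SWD minus BDGS, 66.7% and 83.3% for HH minus BDGS, and 76.7% and 86.7% for SWD minus HH, and 4.44%, 6.25% and 0% of calls were false. Of 200 of 23820 probes changed by 0.5, 68.0%, 68.0% and 67.5% were recovered, with 5.56%, 4.90% and 8.78% of calls false. For camera on 286 families, a list with all members shifted by log2 0.1 reached an adjusted p of 3.41e-15, 3.68e-20 and 3.62e-08, and 0 of 12 unshifted lists passed in each comparison. The noise was drawn independently for each family or probe, and all others were left unchanged. In the data many families differ in both directions, and members of a list may vary together. These rates and p-values therefore do not show how readily the real tests would pass. PERMANOVA gave p under 0.05 in 4 of 100 data sets of 2000 probes without a difference, and exact permutation p-values for 20 variables equalled those of scipy.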

Results

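GeoChip microarrays, which carry oligonucleotide probes for genes of microbial metabolism, were hybridized with DNA from the soil of 3 broad-leaved forests, Saiwudang (SWD), Badagongshan (BDGS) and Houhe (HH), with 9 arrays per forest. Each replicate of a forest had its own array and its own record of soil and vegetation, and is called a plot here. A single site stood for each forest, so forest type and site cannot be separated and the p-values measure the spread between plots. The normalized table held 23820 probes of 345 genes, of which 10107 probes were annotated to carbon cycling, 5292 to organic remediation, 3090 to nitrogen, 1990 to sulfur, 1770 to metals and 1045 to phosphorus. Bacterial sequences accounted for 21145 of these probes, fungal for 1652 and archaeal for 559. The raw intensity summed over an array was 170.1 ± 9.91 in SWD, 180.0 ± 12.3 in BDGS and 146.2 ± 14.3 in HH, in units of 1000000 (mean ± SD, n = 9). The number of arrays limits the precision of each value.

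BDGS soil gave a signal at more probes than the soil of the other two forests. On average 27764 ± 916 probes had a raw value in a BDGS array, against 23956 ± 1079 in SWD and 24430 ± 766 in HH (mean ± SD, n = 9). All 9 SWD arrays and all 9 HH arrays lay below all 9 BDGS arrays. The differences were -3808 and -3335 probes (p = 4.11e-05 in each two-sided exact permutation test, the smallest p these can give), while SWD minus HH was -474 probes (exact permutation p = 0.306). The lowest raw value kept in an array was 379 ± 40.9 units in SWD, 355 ± 20.1 in BDGS and 338 ± 33.9 in HH (mean ± SD, n = 9). Array 9 had the lowest such value and the most probes within SWD (298 units, 26235 probes) and within HH (291 units, 26290 probes). HH had the lowest mean but fewer probes than BDGS. The number of probes at an equal lowest value was not tested. Bacterial probes were detected at 62.7% in SWD, 72.3% in BDGS and 64.0% in HH, archaeal probes at 54.1%, 65.6% and 55.5%, and fungal probes at 54.5%, 65.5% and 55.5%. Among the probes kept by the authors the order was the same, with 22833 ± 509, 23576 ± 159 and 23125 ± 274 detected probes (SWD and HH below BDGS with adjusted p = 0.000617 and 0.0016, exact permutation test). The Shannon index over probes was 10.02 ± 0.0222 in SWD, 10.06 ± 0.00677 in BDGS and 10.04 ± 0.0117 in HH, with adjusted p = 0.00037 for SWD against BDGS, 0.0013 for HH against BDGS and 0.138 for SWD against HH (exact permutation tests, n = 9). Taken over ln values, this index mostly follows the number of detected probes and is not a separate measure of evenness. From the raw table, an alternative fixed beforehand, the index was also lower in SWD than in HH (difference -0.0879, adjusted p = 0.000309, exact permutation test). The same held on linear instead of logarithmic values (-0.0856, adjusted p = 6.17e-05, exact permutation test), a scale chosen after seeing the data.

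**Figure D1:**
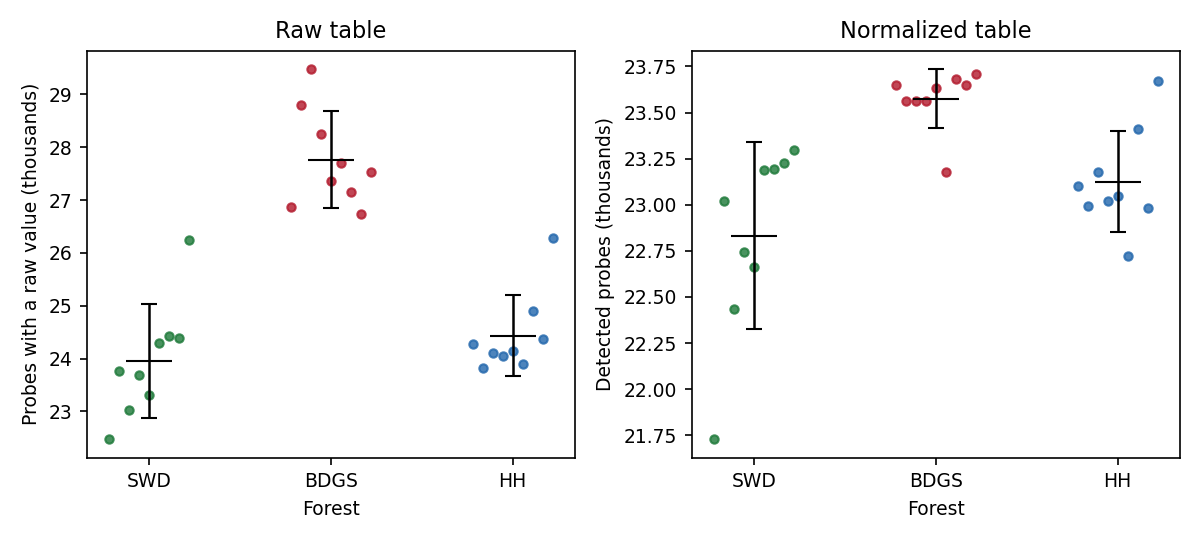
Number of probes detected per array in the raw table and in the normalized table, by forest; points are arrays, bars the mean ± SD of 9 arrays, and the vertical axes do not start at 0. All 9 BDGS arrays lie above all SWD and HH arrays in the raw table.

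The functional structure, meaning the profile of normalized signals over all probes, differed between the 3 forests. Forest accounted for 29.6% of the variation in Bray-Curtis distance (adonis2 permutation test, p = 1e-04, the smallest the permutations can give). By pairs the share was 26.6% for SWD and BDGS, 32.3% for HH and BDGS and 16.0% for SWD and HH, each with permutation p = 1e-04. From gene family sums the shares were 37.7%, 39.4% and 45.8%, and from Jaccard distance on detection 14.7%, 14.4% and 8.77%, the last with adjusted p = 0.0478. Plots also differed in how far they lay from the centre of their forest (permutation p = 0.0003), with mean distances of 0.0245 ± 0.0085 in SWD, 0.0128 ± 0.0047 in BDGS and 0.0186 ± 0.0041 in HH (SD, n = 9), so that the permutation p-values cover location and spread together. SWD arrays were on average no closer to each other (Bray-Curtis 0.0373) than to BDGS or HH arrays (0.0366 for each). SWD array 1 stood apart on the first principal coordinate, at 0.0412 against -0.00025 to 0.0096 in the other SWD arrays. It also had the fewest detected probes of all 27 arrays (21728, against 22437 to 23295 in the other SWD arrays). How far the mean distance within SWD rests on this array was not tested. Mean distances were 0.0194 within BDGS, 0.0281 within HH and 0.0317 between HH and BDGS.

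**Figure D2:**
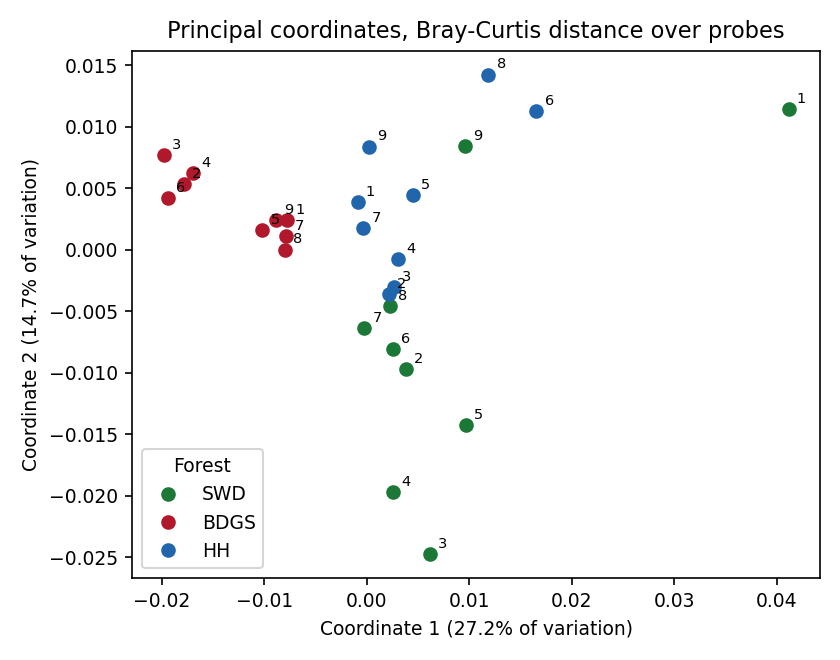
Principal coordinates of the Bray-Curtis distances between the 27 arrays, coloured by forest; the first axis holds 27.2% and the second 14.7% of the variation. Forest accounts for 29.6% of the variation in these distances.

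The soils differed in pH and in nitrogen, phosphorus and iron. Of 45 comparisons of 15 soil and vegetation variables, 29 passed an adjusted p of 0.05 (exact permutation tests, two-sided, adjusted over the 45): 10 for SWD and BDGS, 6 for HH and BDGS, and 13 for SWD and HH. The pH was 6.72 ± 0.717 in HH against 4.12 ± 0.185 in BDGS and 4.48 ± 0.477 in SWD (SD, n = 9), all 9 HH plots lying above all BDGS plots (adjusted p = 0.000123 for HH against either forest, exact permutation test). Nitrate nitrogen was 5.14 ± 5.97 in SWD, 43.5 ± 20.1 in BDGS and 36.4 ± 10.2 in HH, in units not given in the sources used here. Ammonium nitrogen was 41.6 ± 7.16, 83.8 ± 27.7 and 17.1 ± 10.2 in the same order, and each pair differed (adjusted p = 0.00109, 0.000123 and 0.000309 for SWD and BDGS, HH and BDGS, and SWD and HH, exact permutation test). SWD soil held less total phosphorus (0.253 ± 0.0823, against 0.588 ± 0.07 in BDGS and 0.654 ± 0.259 in HH). It also held less total sulfur (0.41 against 1.06 and 0.886) and less iron (13.8 ± 1.94 against 34.2 ± 2.45 and 34.0 ± 9.1). Plant richness was 49.2 ± 12.3 in SWD, 55.8 ± 4.97 in BDGS and 21.4 ± 2.96 in HH.

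**Figure D3:**
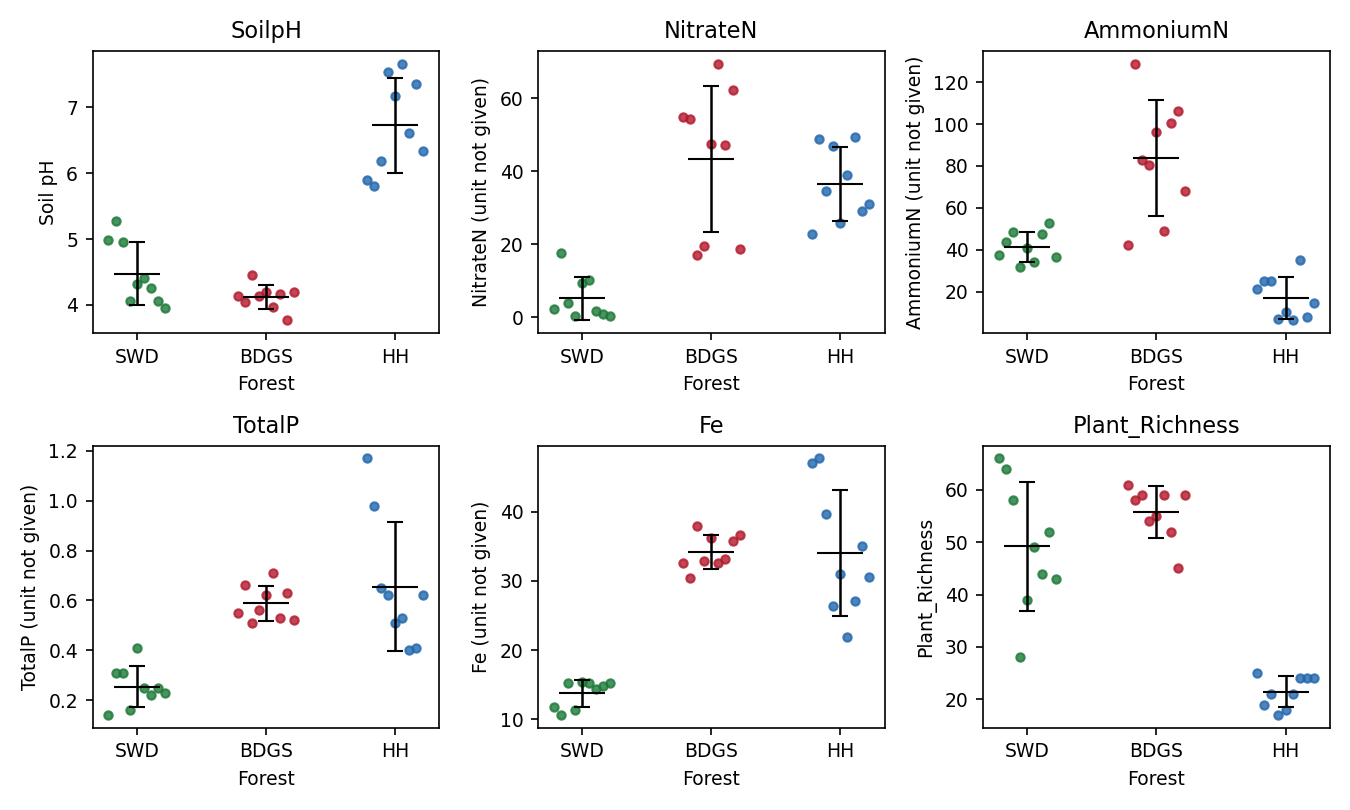
Soil pH, nitrate nitrogen, ammonium nitrogen, total phosphorus, iron and plant richness per plot, by forest, in the units of the deposited table, which gives none; points are plots and bars the mean ± SD of 9 plots. HH has the highest pH (6.72) and SWD the lowest nitrate nitrogen (5.14) and iron (13.8).

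The level of the typical probe differed between forests, and gene differences are therefore given on 2 scales. The median log2 signal of the 18685 probes detected in all 27 arrays was 11.42 ± 0.025 in SWD, 11.60 ± 0.077 in BDGS and 11.49 ± 0.032 in HH (SD, n = 9), although every array summed to the same total. Within BDGS, arrays 2, 3 and 4 stood apart from the other 6. The median difference over all probes was log2 -0.17 for SWD minus BDGS, -0.11 for HH minus BDGS and -0.082 for SWD minus HH. Differences after each array was centred on its median shared probe are called centred below and are relative to that shift. Centring moves every family of a comparison by the same amount, so a lean of centred counts to the higher side is general and not a trait of a list. The shift between forest medians was log2 -0.18 for SWD minus BDGS and -0.10 for HH minus BDGS, and -0.13 and -0.055 without BDGS arrays 2, 3 and 4 (medians of 11.67 to 11.74, against 11.53 to 11.57 in the other 6), so that centred values against BDGS depend in part on 3 arrays. The value of a gene family is the log2 of the summed signal of its probes, in which bright probes weigh most. The shared-probe mean is the mean log2 signal over those of its probes detected in all 27 arrays. Several families that were higher as normalized passed the threshold as lower on this mean, and all of them are named with the effects of the processing. SWD minus BDGS ran from log2 -0.30 in the second decile of shared probes by brightness to 0.077 in the brightest decile, and HH minus BDGS from -0.22 to 0.071. The brightest probes, which weigh most in family sums, thus did not share the fall of the median probe. Centring on that probe can therefore move family sums by more than their own shift. Scaling to an equal total multiplied arrays by a mean factor of 0.970 in SWD, 0.930 in BDGS and 1.14 in HH. Signals are thus relative to the total of an array, and a fall in some probes must come with a rise in others. More or less signal below is meant in this sense, and unscaled intensity may differ in direction.

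**Figure D4:**
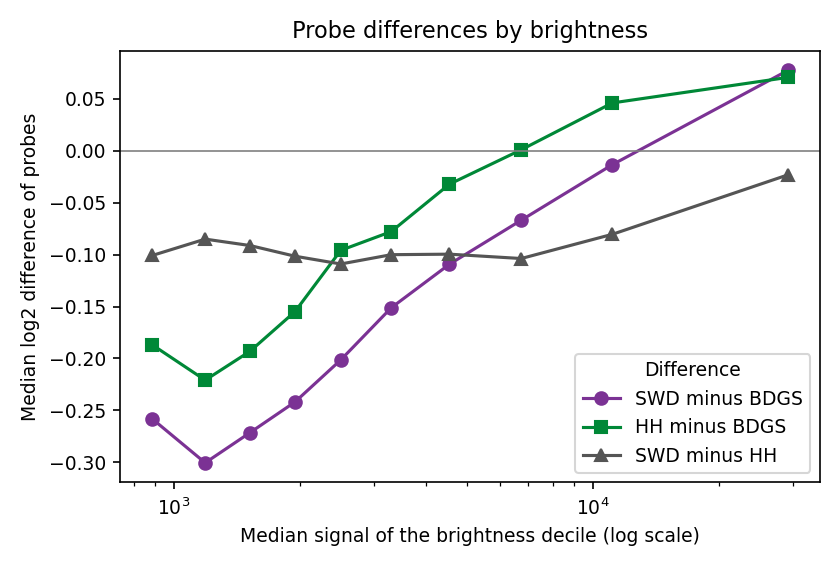
Median log2 difference between forests over the probes detected in all 27 arrays, in deciles of brightness, against the median signal of each decile on a log axis; the lines are the 3 comparisons. Dim probes are lower in SWD and HH than in BDGS (log2 -0.30 and -0.22 in the second decile) and the brightest decile is higher (0.077 and 0.071).

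SWD and BDGS were compared first. SWD soil gave more signal for xlnd, a 3-hydroxybenzoate hydroxylase, at 57424 ± 12683 units against 43432 ± 1748 in BDGS (SD, n = 9). The log2 difference of xlnd was 0.38 ± 0.080 (SE; centred 0.56, limma adjusted p = 0.000332), although its shared-probe mean was lower (-0.090). SWD soil gave less for msad (6883 ± 765 against 9677 ± 766 units, log2 -0.50 ± 0.068, centred -0.31, limma adjusted p = 2.52e-06) and for fosb, a fosfomycin resistance gene (-0.38 ± 0.044, centred -0.20). PEPC and PEP_synthase, annotated to the dicarboxylate/4-hydroxybutyrate cycle of carbon fixation, fell by 0.38 and 0.33 (centred -0.20 and -0.15), Rubisco_Alveolata by 0.36 (centred -0.17) and trza, a triazine hydrolase, by 0.33 (centred -0.15). These families were lower on each of the scales tried. Further families with the largest rises were phdci, annotated to polycyclic aromatics (0.32 ± 0.049), exochitinase (0.31 ± 0.064), C_CoA_hydratase_DiC4HB (0.31 ± 0.068), phospholipase_D_fungi (0.30 ± 0.059) and actin_Perkinsea (0.29 ± 0.066). They had centred values of 0.47 to 0.50 but shared-probe means below BDGS, from -0.25 for phospholipase_D_fungi to -0.0025 for actin_Perkinsea. As shared-probe means xlnd, exochitinase and phospholipase_D_fungi passed as lower in SWD (limma adjusted p = 0.0141, 0.000868 and 4.07e-08). On that mean phdci, C_CoA_hydratase_DiC4HB and actin_Perkinsea did not pass. After quantile normalization C_CoA_hydratase_DiC4HB did not pass (0.16, adjusted p = 0.0597), and exochitinase stood at 0.19 in the centred raw values without passing. PEP_synthase did not pass when centred, and neither it nor trza passed in the centred raw values. A single probe carried 94.8% of the signal of C_CoA_hydratase_DiC4HB, 94.0% of actin_Perkinsea and 71.4% of phdci.

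Nitrogen families past the threshold were higher in some lists and lower in another as normalized. None was lower when centred, which takes the shift of log2 -0.18 off every family alike. In nitrification and ammonia oxidation, 1 of 4 measured families was higher, 0 lower and 3 did not pass (1 past adjusted over the list alone; centred 3 higher, 0 lower). The amoa family, ammonia monooxygenase, rose by 0.21 ± 0.041 (centred 0.39, shared-probe mean -0.15), and hao, hydroxylamine oxidoreductase, stood at -0.070 ± 0.032 without passing (centred 0.11, the other sign). Denitrification had 2 of 5 families higher and 0 lower (2 past adjusted over the list alone; centred 5 higher). The nirs family, a nitrite reductase, stood at 0.11 ± 0.026 (centred 0.29, shared-probe mean -0.14) and narg, a nitrate reductase, at 0.033 ± 0.0099 (centred 0.21, but -0.024 after quantile normalization and -0.11 as shared-probe mean). Nitrate or nitrite reduction outside denitrification had 0 of 6 families higher and 4 lower (4 past adjusted over the list alone), but centred values gave 4 higher and 0 lower. The nasa family stood at -0.13 ± 0.017 and napa at -0.13 ± 0.022, with the other sign when centred (0.051 and 0.054). In nitrogen fixation and ammonification 2 of 3 families rose (2 past adjusted over the list alone; centred 3 higher). The urec family, urease, rose by 0.062 ± 0.013 (centred 0.24) and nifh, nitrogenase, by 0.064 ± 0.025 (centred 0.24), with shared-probe means of -0.11 and -0.13. On that mean amoa, nirs, narg, urec and nifh passed as lower in SWD (limma adjusted p = 0.00117, 2.42e-06, 2.51e-05, 9.83e-06 and 2.15e-05). After quantile normalization neither urec (0.00054, adjusted p = 0.988) nor nifh (0.033, adjusted p = 0.309) passed. The nifh family also did not pass with the replicate number as a block, with array weights or in a fit to these 2 forests alone.

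Carbon degradation families that changed were mostly lower in SWD on the normalized scale and higher after centring, as were families in general. Starch degradation had 0 of 5 families higher and 3 lower (4 past adjusted over the list alone; centred 3 higher, 0 lower). The pula family, pullulanase, stood at -0.14 ± 0.026 (centred 0.040, -0.011 from the centred raw table) and amyA, alpha-amylase, at -0.033 ± 0.0093 (centred 0.15). Cellulose and hemicellulose degradation had 0 of 8 higher and 3 lower (3 past adjusted over the list alone; centred 6 higher, 0 lower). The xylanase family stood at -0.13 ± 0.025 (centred 0.047) and cellobiase at -0.11 ± 0.027 (centred 0.069). In chitin and pectin degradation 4 of 13 rose, exochitinase among them, and 5 fell (9 past adjusted over the list alone; centred 10 higher, 0 lower). The pme family, pectin methylesterase, rose by 0.086 ± 0.015 (centred 0.27, shared-probe mean -0.13) and endopolygalacturonase_fungi stood at -0.16 ± 0.032 (centred 0.016, -0.021 from the centred raw table). Lignin and aromatic carbon degradation had 1 of 11 higher and 3 lower (4 past adjusted over the list alone; centred 9 higher, 0 lower). The ligninase family stood at -0.19 ± 0.037 and lmo, annotated to terpenes, at -0.20 ± 0.058, both still just below BDGS when centred (-0.010 and -0.014). Among carbon fixation families 1 of 10 was higher and 4 lower (5 past adjusted over the list alone; centred 7 higher, 1 lower). The mcl family, malyl-CoA lyase, stood at -0.16 ± 0.041 (centred 0.018). Methane cycling had 1 of 5 higher and 2 lower (3 past adjusted over the list alone; centred 4 higher, 0 lower). The pmoa family, particulate methane monooxygenase, stood at -0.10 ± 0.019 (centred 0.080), and mdh, which the array annotates to carbon fixation, at 0.21 ± 0.041 (centred 0.39, shared-probe mean -0.32), with 82.4% of its signal from a single probe. After quantile normalization pme (0.015, adjusted p = 0.657), mcl (-0.053, adjusted p = 0.241) and mdh (0.092, adjusted p = 0.13) did not pass. As shared-probe means pme and mdh passed as lower in SWD (limma adjusted p = 6.38e-06 and 3.58e-05).

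Sulfur families split, with 3 of 14 higher, 3 lower and 8 not past (6 past adjusted over the list alone; centred 14 higher, 0 lower). The aps_apra family, adenylylsulfate reductase, rose by 0.13 ± 0.020 (centred 0.31, shared-probe mean -0.040) and dsrB, dissimilatory sulfite reductase, stood at -0.10 ± 0.021 (centred 0.083). Phosphorus utilization had 0 of 3 higher and 1 lower (1 past adjusted over the list alone; centred 3 higher, 0 lower). The ppk family, polyphosphate kinase, stood at -0.066 ± 0.010 (centred 0.11), while ppx, exopolyphosphatase, stood at -0.023 ± 0.010 without passing (adjusted p = 0.067, centred 0.16). Metal resistance had 0 of 6 higher and 2 lower (2 past adjusted over the list alone; centred 6 higher, 0 lower). The merb family, organomercurial lyase, stood at -0.13 ± 0.023 (centred 0.054) and arsc, arsenate reductase, at -0.051 ± 0.016 (centred 0.13). Among single probes past the threshold in limma (n = 9 per forest), the endochitinase probe of Vibrio angustum read 2284 ± 1007 units in SWD against 622 ± 154 in BDGS (log2 1.76 ± 0.22). The xylg probe of Pseudomonas read 13356 ± 4088 against 3961 ± 538 (1.72 ± 0.12). Lower readings came from the amyA probe of Bacillus pseudofirmus (719 ± 119.9 against 3053 ± 682, -2.06 ± 0.14) and the pme_Cdeg probe of Penicillium chrysogenum (1221 ± 206 against 4308 ± 1950.1, -1.73 ± 0.17). Of 286 families tested in limma, 152 passed, 50 higher and 102 lower in SWD. The split was 195 higher and 20 lower when centred, 181 and 33 from the centred raw values, 25 and 117 after quantile normalization, and 3 and 246 as shared-probe means. Of 23820 probes, 2151 were higher and 9719 lower, against 5525 and 4872 when centred, 5634 and 4909 from the centred raw table and 2979 and 6260 after quantile normalization. Without BDGS arrays 2, 3 and 4, which stood apart, 144 families passed, 51 higher and 93 lower.

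**Figure D5:**
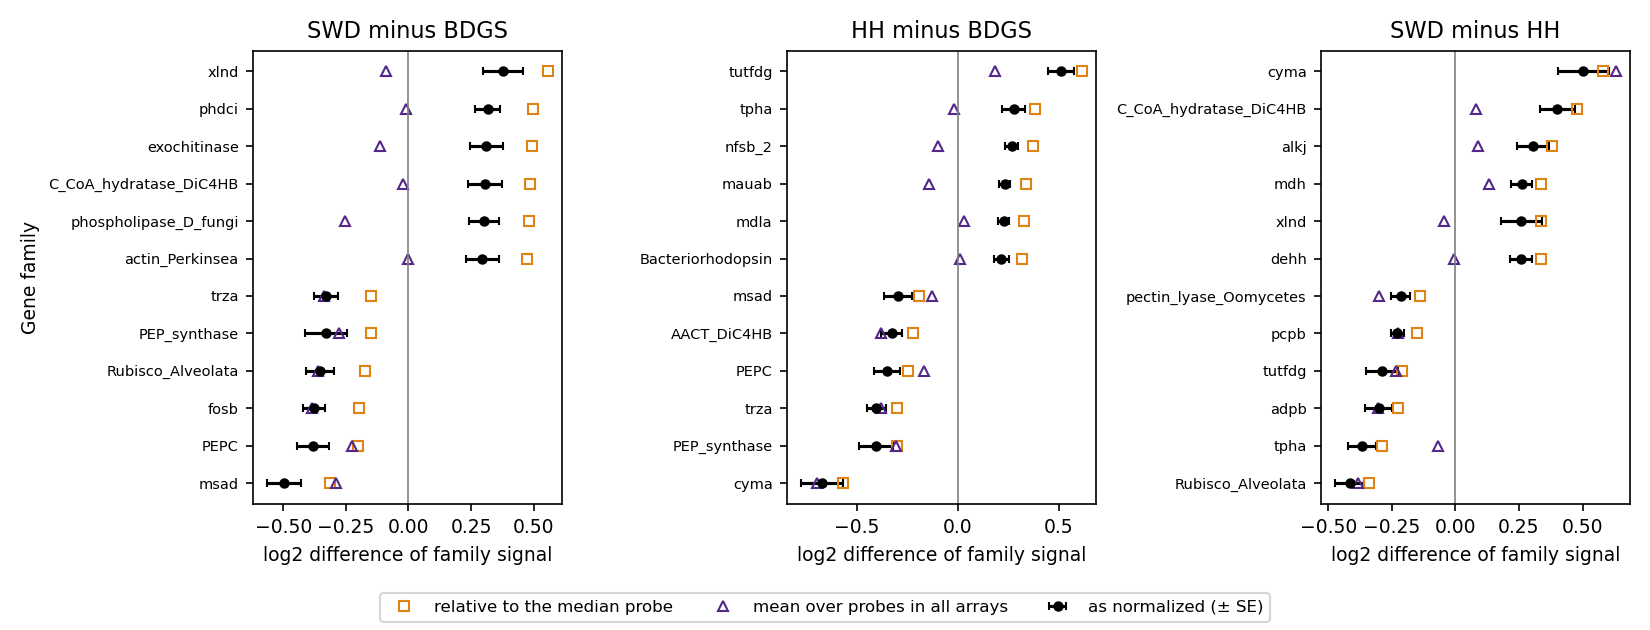
Log2 differences of the gene families with the largest changes in each comparison: black points as normalized ± SE, orange squares relative to the median probe, purple triangles the mean over probes detected in all 27 arrays. The triangle lies below 0 for all 6 families that rose in SWD minus BDGS (xlnd -0.090, phospholipase_D_fungi -0.25), for tpha, nfsb_2 and mauab in HH minus BDGS, and for xlnd and dehh in SWD minus HH.

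HH and BDGS differed in tutfdg and cyma, among other families. HH soil gave more signal for tutfdg, the activation of toluene, at 33318 ± 2555 units against 23359 ± 1107 (SD, n = 9; log2 0.51 ± 0.063, centred 0.61, shared-probe mean 0.18, limma adjusted p = 6.63e-07). It gave less for cyma, the oxidation of p-cymene, at 10700.4 ± 951 against 17115 ± 2262 (log2 -0.67 ± 0.10, centred -0.57, limma adjusted p = 6.83e-06). Rises were also seen in mdla, mandelate racemase (0.23 ± 0.029, centred 0.33), and Bacteriorhodopsin, a light-driven proton pump (0.22 ± 0.035, centred 0.32), but their shared-probe means were only 0.029 and 0.0092 and did not pass. The rises of tpha, terephthalate dioxygenase (0.28 ± 0.055), nfsb_2, a nitroreductase (0.27 ± 0.032), and mauab, methylamine dehydrogenase (0.23 ± 0.027), had centred values of 0.38, 0.37 and 0.34 but shared-probe means of -0.019, -0.096 and -0.14. On that mean nfsb_2 and mauab passed as lower in HH (limma adjusted p = 0.00533 and 0.00028), and tpha did not pass. PEP_synthase, trza, PEPC, AACT_DiC4HB and msad fell by 0.40, 0.40, 0.35, 0.33 and 0.29 (centred -0.30, -0.30, -0.24, -0.22 and -0.19), and were lower on each of the scales tried.

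In nitrification and ammonia oxidation 0 of 4 families were higher and 1 was lower in HH (1 past adjusted over the list alone; centred 1 higher, 0 lower). The hzo family, hydrazine oxidation by anammox bacteria, stood at -0.21 ± 0.064 (centred -0.11), and hzsa at -0.15 ± 0.066 without passing (adjusted p = 0.0531), with the other sign in the centred raw table (0.22). Denitrification had 2 of 5 families higher and 0 lower (2 past adjusted over the list alone; centred 4 higher). The narg family stood at 0.056 ± 0.0099 (centred 0.16, shared-probe mean 0.012) and norb, nitric oxide reductase, at 0.076 ± 0.020 (centred 0.18, shared-probe mean -0.074). The other nitrate or nitrite reduction families had 0 of 6 higher and 2 lower (2 past adjusted over the list alone; centred 3 higher, 0 lower). The nirb family stood at -0.10 ± 0.020 and nasa at -0.043 ± 0.017, both with the other sign when centred (0.0034 and 0.061). In nitrogen fixation and ammonification 2 of 3 rose and 1 fell (3 past adjusted over the list alone; centred 2 higher, 0 lower). The urec family rose by 0.044 ± 0.013 (centred 0.15, shared-probe mean -0.033), and nifh stood at -0.067 ± 0.025 (centred 0.037, -0.017 from the centred raw table). After quantile normalization narg (0.024, adjusted p = 0.193), norb (0.041, adjusted p = 0.173), urec (0.0047, adjusted p = 0.812), nasa (-0.034, adjusted p = 0.245) and hzo (-0.12, adjusted p = 0.0863) did not pass. Leaving out BDGS arrays 2, 3 and 4 also ended the calls of hzo, nasa and nifh, and nifh did not pass with the replicate number as a block.

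Cellulose and hemicellulose degradation had 4 of 8 families higher and 2 lower in HH (6 past adjusted over the list alone; centred 5 higher, 0 lower). The ara family, arabinofuranosidase, stood at 0.073 ± 0.015 (centred 0.18, shared-probe mean -0.054) and exoglucanase at -0.13 ± 0.028 (centred -0.031). Starch degradation had 1 of 5 higher and 1 lower (2 past adjusted over the list alone; centred 4 higher, 0 lower). The glucoamylase family stood at 0.057 ± 0.021 (centred 0.16, shared-probe mean -0.12) and pula at -0.12 ± 0.026 (centred -0.021). Chitin and pectin degradation had 1 of 13 higher and 7 lower (8 past adjusted over the list alone; centred 5 higher, 0 lower). The acetylglucosaminidase family stood at -0.061 ± 0.013 and chitinase at -0.065 ± 0.015, which had the other sign when centred (0.043 and 0.039). Lignin and aromatic carbon degradation had 2 of 11 higher and 0 lower (2 past adjusted over the list alone; centred 9 higher). The vana family, vanillate demethylase, stood at 0.077 ± 0.016 (centred 0.18) and mnp, manganese peroxidase, at 0.12 ± 0.028 (centred 0.22), with shared-probe means of -0.053 and -0.087. Carbon fixation had 3 of 10 higher and 2 lower (5 past adjusted over the list alone; centred 7 higher, 0 lower). The TIM family, triosephosphate isomerase, stood at 0.089 ± 0.016 (centred 0.19, shared-probe mean -0.040) and fthfs, formyltetrahydrofolate synthetase, at -0.12 ± 0.024 (centred -0.015). After quantile normalization vana (0.037, adjusted p = 0.166) and glucoamylase (0.037, adjusted p = 0.225) did not pass. Methane cycling had 1 of 5 higher and 1 lower (2 past adjusted over the list alone; centred 2 higher, 0 lower). The pmoa family stood at -0.12 ± 0.019 (centred -0.021) and mdh_DiC4HB, annotated to carbon fixation, at 0.14 ± 0.057 (centred 0.25).

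Sulfur cycling had 1 of 14 families higher and 4 lower in HH (5 past adjusted over the list alone; centred 5 higher, 0 lower). The dsra family stood at -0.076 ± 0.013 (centred 0.027, -0.0043 from the centred raw table) and Sir, sulfite reductase, at -0.080 ± 0.014 (centred 0.024). Phosphorus utilization had 1 of 3 higher and 1 lower (2 past adjusted over the list alone; centred 3 higher, 0 lower). The phytase family, which releases phosphate from phytate, rose by 0.10 ± 0.022 (centred 0.20, shared-probe mean -0.12), and ppk stood at -0.048 ± 0.010 (centred 0.056). Metal resistance had 2 of 6 higher and 0 lower (2 past adjusted over the list alone; centred 5 higher). The aoxb family, arsenite oxidase, stood at 0.070 ± 0.015 (centred 0.17, shared-probe mean -0.035) and arsm, arsenite methyltransferase, at 0.11 ± 0.029 (centred 0.21, shared-probe mean -0.026). After quantile normalization aoxb did not pass (0.045, adjusted p = 0.0605). Among single probes past the threshold, the largest rises were in a hao probe of an uncultured bacterium (4643 ± 1719.6 units in HH against 972 ± 655, log2 2.42 ± 0.31) and the tfda probe of Mycobacterium tusciae (3584 ± 705 against 902 ± 209, 2.01 ± 0.16). Lower in HH were the arsc probe of Serratia proteamaculans (1728 ± 228 against 6900.4 ± 1476, -1.98 ± 0.16) and the arylest probe of Shewanella baltica (1719 ± 257 against 6517 ± 1578, -1.90 ± 0.16). In limma 142 of 286 families passed, 66 higher and 76 lower, against 153 and 25 when centred, 137 and 34 from the centred raw table, 42 and 88 after quantile normalization and 16 and 181 as shared-probe means. Of 23820 probes, 4131 were higher and 8250 lower, against 6075 and 5905 when centred and 6200 and 6005 from the centred raw table. Without BDGS arrays 2, 3 and 4, 132 families passed, 68 higher and 64 lower. Among the families named for this comparison, hzo, nasa, nifh and glucoamylase no longer passed without these arrays, and nifh also did not pass with the replicate number as a block.

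SWD and HH differed in cyma and Rubisco_Alveolata, among other families. SWD soil gave 15428 ± 3335 units for cyma against 10700.4 ± 951 in HH (SD, n = 9; log2 0.50 ± 0.10, centred 0.58, shared-probe mean 0.63, limma adjusted p = 0.000314). For Rubisco_Alveolata it gave 10363 ± 728 against 13811 ± 706 (log2 -0.42 ± 0.056, centred -0.34, limma adjusted p = 3.15e-06). Rises were found in C_CoA_hydratase_DiC4HB (0.40 ± 0.068, centred 0.48), alkj, an alcohol dehydrogenase of alkane oxidation (0.30 ± 0.064, centred 0.38), and mdh (0.26 ± 0.041, centred 0.34), with shared-probe means of 0.082, 0.089 and 0.13, none of them past the threshold. The sums of natural logs had the other sign for cyma (-0.085), C_CoA_hydratase_DiC4HB (-0.037) and mdh (-0.074). The rises of xlnd (0.26 ± 0.080, centred 0.34) and dehh, a haloacid dehalogenase (0.26 ± 0.042, centred 0.34), came with shared-probe means of -0.044 and -0.0067. SWD had less signal for tpha (-0.37 ± 0.055, centred -0.29), adpb, annotated to pesticides (-0.30 ± 0.053, centred -0.22), tutfdg (-0.29 ± 0.063, centred -0.21), pcpb, pentachlorophenol monooxygenase (-0.23 ± 0.026, centred -0.15), and pectin_lyase_Oomycetes (-0.22 ± 0.037, centred -0.14).

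Nitrification and ammonia oxidation had 1 of 4 families higher in SWD and 0 lower (1 past adjusted over the list alone; centred 4 higher). The amoa family stood at 0.20 ± 0.041 (centred 0.27, shared-probe mean 0.077), with hzsa at 0.15 ± 0.066 without passing (adjusted p = 0.0666). Denitrification had 2 of 5 higher and 1 lower (4 past adjusted over the list alone; centred 3 higher, 0 lower). The nirk family stood at 0.070 ± 0.022 (centred 0.15, shared-probe mean -0.078) and norb at -0.075 ± 0.020 (centred 0.0020, -0.0025 from the centred raw table). Other nitrate or nitrite reduction had 0 of 6 higher and 3 lower (3 past adjusted over the list alone; centred 1 higher, 0 lower). The napa family stood at -0.11 ± 0.022 (centred -0.035) and nasa at -0.086 ± 0.017 (centred -0.0094). In nitrogen fixation and ammonification 1 of 3 was higher and 0 lower (1 past adjusted over the list alone; centred 2 higher). The nifh family rose by 0.13 ± 0.025 (centred 0.21, shared-probe mean -0.0047), and urec stood at 0.017 ± 0.013 without passing (centred 0.094, -0.0041 after quantile normalization). After that normalization norb (-0.052, adjusted p = 0.0885) and nasa (-0.044, adjusted p = 0.148) did not pass.

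Chitin and pectin degradation had 6 of 13 families higher in SWD and 1 lower (10 past adjusted over the list alone; centred 8 higher, 0 lower). The endochitinase family stood at 0.25 ± 0.037 (centred 0.33) and pectinase (pectate_lyase) at 0.057 ± 0.013 (centred 0.13), with shared-probe means of -0.047 and -0.0050, and pectinase (pectate_lyase) did not pass after quantile normalization (0.0019, adjusted p = 0.95). Lignin and aromatic carbon degradation had 1 of 11 higher and 5 lower (6 past adjusted over the list alone; centred 2 higher, 1 lower). The mnp family stood at -0.16 ± 0.028 (centred -0.080) and ligninase at -0.19 ± 0.037 (centred -0.11). Cellulose and hemicellulose degradation had 1 of 8 higher and 4 lower (8 past adjusted over the list alone; centred 2 higher, 0 lower). The endoglucanase family stood at -0.10 ± 0.013 (centred -0.022) and ara at -0.059 ± 0.015 (centred 0.018, the other sign). Starch degradation had 0 of 5 higher and 3 lower (3 past adjusted over the list alone; centred 1 higher, 0 lower). The glucoamylase family stood at -0.11 ± 0.021 (centred -0.034) and amyA at -0.033 ± 0.0093 (centred 0.044, the other sign). Carbon fixation had 0 of 10 higher and 3 lower (3 past adjusted over the list alone; centred 3 higher, 1 lower). Besides Rubisco_Alveolata, pgk, phosphoglycerate kinase, stood at -0.075 ± 0.019 (centred 0.0019, -0.00039 from the centred raw table). Methane cycling had 1 of 5 higher and 2 lower (3 past adjusted over the list alone; centred 2 higher, 0 lower). The family that rose was mdh, and mmox, soluble methane monooxygenase, stood at -0.13 ± 0.032 (centred -0.056).

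Sulfur cycling had 5 of 14 families higher in SWD and 1 lower (6 past adjusted over the list alone; centred 9 higher, 1 lower). The aps_apra family stood at 0.12 ± 0.020 (centred 0.19, shared-probe mean -0.0010) and SoxB, of thiosulfate oxidation, at -0.17 ± 0.023 (centred -0.093). Phosphorus utilization had 0 of 3 higher and 1 lower (0 past adjusted over the list alone; centred 2 higher, 0 lower). The phytase family stood at -0.054 ± 0.022 (centred 0.023, the other sign), with ppk at -0.018 ± 0.010 without passing (centred 0.059). Metal resistance had 0 of 6 higher and 4 lower (4 past adjusted over the list alone; centred 1 higher, 1 lower). The merb family stood at -0.15 ± 0.023 (centred -0.068) and aoxb at -0.070 ± 0.015 (centred 0.0073, the other sign). Among single probes past the threshold, the chitinase probe of Salmonella bongori stood at 7822 ± 1584 units in SWD against 1967 ± 384 in HH (log2 1.99 ± 0.15) and the cyma probe of Burkholderia xenovorans at 5026 ± 3084 against 1250.4 ± 115.6 (1.77 ± 0.24). Lower in SWD were the urec probe of Arthrobacter chlorophenolicus at 1701 ± 449.7 against 8486 ± 3022 (-2.26 ± 0.18) and a phenol_oxidase probe of an uncultured bacterium at 737 ± 156 against 2648 ± 1475 (-1.70 ± 0.21). In limma 138 of 286 families passed, 49 higher and 89 lower in SWD, against 99 and 24 when centred, 96 and 29 from the centred raw table and 10 and 148 as shared-probe means. Quantile normalization left 104 families past the threshold. Of 23820 probes, 2139 were higher and 5238 lower, against 3227 and 3091 when centred and 3238 and 3079 from the centred raw table.

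In limma's camera, which compares a list with the other families, 0 of 39 tests of 13 fixed lists passed (smallest adjusted p = 0.354), with 5 at an unadjusted p under 0.05. These were denitrification (up), nitrate or nitrite reduction (down) and nitrogen fixation and ammonification (up) in SWD minus BDGS, and chitin and pectin degradation and sulfur cycling (both up) in SWD minus HH. With an estimated correlation 0 passed as well, the smallest adjusted p being 0.444 for chitin and pectin degradation in SWD minus HH. Of 102 tests of 34 lists taken from the array's own annotation, 0 passed in camera (smallest adjusted p = 0.495, 3 with an unadjusted p under 0.05). Median, mean and camera direction of a list differed in sign for nitrification, chitin and pectin, methane and sulfur in SWD minus BDGS, for phosphorus in HH minus BDGS, and for denitrification in SWD minus HH. The fixed lists of stress genes and of antibiotic resistance genes matched 0 families of the table by name. The array's own annotation nevertheless holds 6 tested families of antibiotic resistance, fosb among them, under other names.

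Bacterial probes carried a larger share of the signal in HH, and fungal probes a smaller one. The bacterial share was 90.76 ± 0.117% in HH against 90.48 ± 0.138% in BDGS and 90.44 ± 0.164% in SWD. The fungal share was 5.86 ± 0.0941% against 6.05 ± 0.0991% and 6.11 ± 0.145% (SD, n = 9; adjusted p = 0.00268 against BDGS and 0.00241 against SWD for both, exact permutation tests over 9 comparisons). The archaeal share was 2.06 ± 0.0296% in SWD and 2.02 ± 0.0354% in HH (adjusted p = 0.0452, exact permutation test), and no share passed between SWD and BDGS. Counted as shares of detected probes, 1 of 9 comparisons passed, Bacteria in SWD minus BDGS (0.0632 percentage points, adjusted p = 0.00629, exact permutation test). No comparison with HH passed on that count. The differences of SWD minus HH and of SWD minus BDGS had the other sign in all 3 domains.

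Soil and vegetation variables were also tested within forests. After forest, 0 of 15 variables passed in the adonis2 test with permutations within forests, 2 having an unadjusted p under 0.05. Total phosphorus accounted for 4.72% of the variation (permutation p = 0.0218) and nitrate nitrogen for 3.00% (p = 0.0473), both with adjusted p = 0.187. Of 4290 tests of a family against a variable within forests, 3 passed in limma, adjusted over families for each variable, and 343 had an unadjusted p under 0.05. The families of biphenyl degradation bphb and bphd changed with plant Shannon diversity by log2 0.081 ± 0.017 (adjusted p = 0.0214) and -0.048 ± 0.011 (adjusted p = 0.027) per SD of the variable, and tutfdg with plant richness by 0.21 ± 0.042 (adjusted p = 0.00784). These 3 relations were chosen after their values were seen, and without BDGS arrays 2, 3 and 4 the count was 6.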

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

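The 5 tests of the excess in BDGS, with the deciles one of them compares, and the counts of the 705 probes by gene, category, domain and phylum were tests chosen only after the result was seen.

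In 294 groups of 9 arrays or plots, the highest or lowest value was set against the rest, and in 24 its gap to the nearest other was a larger share of the group's range than the 95% bound. Chance alone gives about 1 in 20 groups, so 24 of 294 is above that share, although the values of one array are not independent. BDGS array 6 held 11 of the 24. Its number of detected probes was the lowest of BDGS (23178 against 23561 to 23709 in the others, gap 0.721 of the range), as was its Shannon index (gap 0.769), which mostly follows that number. Its family signals stood lowest for phytase (0.670), vana (0.627), narg (0.511) and TIM (0.507), and highest for fthfs (0.822), cellobiase (0.761), xylanase (0.702), alkj (0.546) and nirk (0.535). HH array 6 stood highest for arsm (0.612), Bacteriorhodopsin (0.573), narg (0.538) and pgk (0.527). HH array 7 stood highest for acetylglucosaminidase (0.627) and lowest for ara (0.618), and its plot had the highest organic carbon (101.6 against 41.02 to 64.89, gap 0.606). HH array 9 had the most probes with a raw value (26290 against 23828 to 24905, gap 0.563) and the lowest signal for phospholipase_D_fungi (0.722). Its lowest raw value, 291 units, was also the lowest of the HH arrays. SWD array 9 stood highest for endopolygalacturonase_fungi (0.514) and lowest for phytase (0.528). Available phosphorus was highest in SWD plot 2 (0.526) and plant evenness lowest in BDGS plot 9 (0.519). No explanation of these was tested.

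More probes had a raw value in BDGS, and dim probes were brighter there. BDGS arrays 2, 3 and 4 carried part of the excess in dim probes (409 to 495 units at the third decile of brightness, against 144 to 222 in the other 6) but not all of it, since the other 6 exceeded SWD by log2 0.18 over the 5 dimmer deciles of shared probes (SE 0.013; 0.25 with all 9). Total intensity does not account for it as a whole: at equal raw total BDGS had 3735 more probes than SWD (SE 471) and 3084 more than HH (SE 692), and its dim probes were brighter than in SWD by 0.23 (SE 0.032). Nor does scaling account for the dim probes, which were brighter than in SWD by 0.31 before it (SE 0.045). The lowest raw value kept was lower on average in BDGS than in SWD but higher than in HH. It was not tested as an account of the number of probes. An offset of background in BDGS stays open. From the third to the fifth decile the linear excess rose by 46.5 units over SWD (SE 2.97, in 9 of 9 BDGS arrays), against a constant offset. Over HH it changed by -29.7 (SE 7.81, a rise in 1 of 9), and the lack of a rise had been set as what an offset allows. The comparison with HH cannot decide, since the values had been scaled by a mean factor of 0.930 in BDGS and 1.14 in HH. Such scaling alone can change the excess with brightness. Labelling, hybridization or a batch, none of which the labels give, cannot be told apart from the forest. A difference in the soil community stays open as untested.

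A signal was also seen in probes outside the normalized table. Of these, 705 had a raw value in at least 7 BDGS arrays and in at most 1 array of each other forest, against 10 such probes for HH and 3 for SWD. Their median raw value was 599, at percentile 9.31 of the values of the same arrays (quartiles 4.30 and 16.3), just under the 10th percentile set as a bound beforehand. This is consistent with probes near the detection limit that crossed it in BDGS, although some lay well above it. Actinobacteria made up 58 of them, or 1.11% of the 5210 Actinobacteria probes of the raw table, against 1.92% of its other probes (Fisher's exact test, adjusted p = 0.000477). They were the only phylum to pass, and no gene, category or domain of life passed. A difference in the soil community stays open as untested.

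Splits of the arrays into other groups of the same sizes were counted for the fits, 100 drawn at random with the real one included. For families differing between SWD and BDGS 1 split, the real one, gave as many (152, highest other 122, a split with 1 array of each forest exchanged), and likewise for HH and BDGS (142, highest other 0) and for SWD and HH (138, highest other 14). For probes the real split was again the 1 with as many, at 11870 (highest other 6764), 12381 (highest other 1) and 7377 (highest other 490). A random division of these arrays is therefore unlikely to give such counts, as far as 100 splits can show. The splits do not bear on whether a single site stands for its forest. For the fixed lists in camera 0 passed (5 at an unadjusted p under 0.05), and 100 of 100 regroupings gave as many (highest other 0), which decides nothing.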

How the results depend on the processing

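Centring on the median probe, the log2 of summed natural logs, linear values for the Shannon index, linear Bray-Curtis distance, a methane list without mdh, leaving out BDGS arrays 2, 3 and 4, and, for gene lists, quantile normalization and shared-probe means were tests chosen only after the results were seen.

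For the 111 comparisons of named families, 1411 values under alternatives were computed: 1142 kept their direction and their side of the threshold, 114 lost the call, 19 gained it and 136 changed sign, 6 of these without a call in either setting. Of the lost calls, 26 were under the log2 of summed natural logs, 20 in the centred raw values, 17 under quantile normalization, 17 under the mean signal per detected probe, 14 when centred and 11 as shared-probe means. All alternatives fixed beforehand were run. The other filters on families left the value of each family as it was, and all values under them were kept (111 without a filter and 79 with at least 10 detected probes). These, like the values under division by the array total, are among the 1142, so that count overstates stability. Division by the array total moved nothing, since the totals were already equal, and says nothing about stability. Family counts otherwise ran from 103 to 249 (152 as reported) for SWD minus BDGS, from 95 to 197 (142) for HH minus BDGS and from 51 to 161 (138) for SWD minus HH, and probe counts from 8955 to 12145 (11870), 10471 to 12732 (12381) and 6317 to 8316 (7377). No alternative gave a fixed list past the threshold in camera, or a variable past it for functional structure in the adonis2 or Mantel tests. Soil and vegetation differences past the threshold numbered 28 to 30 (29 as reported). How far the signal of a probe stood above its background was not analysed here, so a limit from depth is not given.

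The mean log2 over probes detected in all 27 arrays, which gives dim and bright probes equal weight, raised the count of families in SWD minus BDGS to 249. It turned the sign of families that had been higher. In SWD minus BDGS these were xlnd -0.090, phdci -0.0081, exochitinase -0.11, C_CoA_hydratase_DiC4HB -0.022, phospholipase_D_fungi -0.25, actin_Perkinsea -0.0025, amoa -0.15, nirs -0.14, narg -0.11, urec -0.11, nifh -0.13, pme -0.13, mdh -0.32 and aps_apra -0.040. In HH minus BDGS these were tpha -0.019, nfsb_2 -0.096, mauab -0.14, norb -0.074, urec -0.033, glucoamylase -0.12, ara -0.054, vana -0.053, mnp -0.087, TIM -0.040, phytase -0.12, aoxb -0.035 and arsm -0.026. In SWD minus HH these were xlnd -0.044, dehh -0.0067, nirk -0.078, nifh -0.0047, urec -0.080, endochitinase -0.047, pectinase (pectate_lyase) -0.0050 and aps_apra -0.0010. Of the families turned in SWD minus BDGS, all passed as lower in limma except phdci, C_CoA_hydratase_DiC4HB, actin_Perkinsea and aps_apra. Of those turned in HH minus BDGS, all did except tpha, urec, vana, aoxb and arsm. Of those turned in SWD minus HH, only nirk and urec did. The cause was not tested.

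The log2 of summed natural logs lowered the count in SWD minus HH to 51. With it the sign turned for SWD minus BDGS in the families xlnd -0.011, phdci -0.016, exochitinase -0.058, C_CoA_hydratase_DiC4HB -0.036, phospholipase_D_fungi -0.038, actin_Perkinsea -0.0074, amoa -0.076, nirs -0.067, narg -0.048, urec -0.055, nifh -0.083, pme -0.083, mdh -0.090 and aps_apra -0.055. For HH minus BDGS it turned in tpha -0.0023, nfsb_2 -0.038, mauab -0.017, mdla -0.0032, Bacteriorhodopsin -0.0014, narg -0.013, norb -0.0094, urec -0.028, glucoamylase -0.041, ara -0.037, vana -0.014, TIM -0.028, phytase -0.036, aoxb -0.040 and arsm -0.040. For SWD minus HH it turned in cyma -0.085, C_CoA_hydratase_DiC4HB -0.037, mdh -0.074, xlnd -0.0055, dehh -0.0093, nirk -0.023, nifh -0.024, urec -0.027, endochitinase -0.0052, pectinase (pectate_lyase) -0.022 and aps_apra -0.014. The cause was not tested.

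Centring each array on its median shared probe turned the sign of families that had been lower, since it takes off the shift of the median probe between forests. For SWD minus BDGS the centred values were hao 0.11, nasa 0.051, napa 0.054, pula 0.040, amyA 0.15, xylanase 0.047, cellobiase 0.069, endopolygalacturonase_fungi 0.016, mcl 0.018, pmoa 0.080, ppk 0.11, ppx 0.16, dsrB 0.083, merb 0.054 and arsc 0.13. For HH minus BDGS the centred values were nirb 0.0034, nasa 0.061, nifh 0.037, acetylglucosaminidase 0.043, chitinase 0.039, ppk 0.056, dsra 0.027 and Sir 0.024. For SWD minus HH the centred values were norb 0.0020, amyA 0.044, ara 0.018, pgk 0.0019, phytase 0.023, ppk 0.059 and aoxb 0.0073.

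From the centred raw values the sign turned as well. Those values in SWD minus BDGS were hao 0.091, nasa 0.025, napa 0.019, amyA 0.13, xylanase 0.026, cellobiase 0.041, mcl 0.018, pmoa 0.013, ppk 0.065, ppx 0.14, dsrB 0.091, merb 0.052 and arsc 0.11. Those values in HH minus BDGS were hzsa 0.22, nirb 0.024, nasa 0.038, acetylglucosaminidase 0.026, chitinase 0.018, ppk 0.0079 and Sir 0.020. Those values in SWD minus HH were amyA 0.043, ara 0.016, phytase 0.030, ppk 0.057 and aoxb 0.0030. Quantile normalization turned narg in SWD minus BDGS (-0.024) and urec in SWD minus HH (-0.0041). The mean signal per detected probe turned amyA (0.011), hao (0.064) and ppx (0.035) in SWD minus BDGS and ppk (0.012) in SWD minus HH. The causes were not tested.

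As a share of detected probes, 1 domain comparison, Bacteria in SWD minus BDGS, passed instead of 5 others. The difference turned for Bacteria (0.0632 percentage points), Archaea (-0.00808) and Fungi (-0.0437) in SWD minus BDGS and, in SWD minus HH, for Bacteria (0.0216), Archaea (-0.00185) and Fungi (-0.0157). The Shannon index was also lower in SWD than in HH from the raw table, an alternative fixed beforehand (-0.0879, adjusted p = 0.000309, exact permutation test), and from linear values (-0.0856, adjusted p = 6.17e-05). On ranks, total phosphorus turned in HH minus BDGS (-0.333), without a call on either scale. Without BDGS arrays 2, 3 and 4, families related to a variable within forests numbered 6 instead of 3, and hzo, nasa, nifh and glucoamylase lost their call in HH minus BDGS. Without these arrays plant evenness turned in SWD minus BDGS (0.0104), with no call in either case. The cause was not tested.

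Of the fixed lists, which never passed in camera, the direction in camera turned in some settings. Each is given here with the median log2 difference of its members minus that of the other families, which need not have the same sign as camera. Under the mean signal per detected probe it turned for SWD minus BDGS, cellulose and hemicellulose degradation (0.016), lignin and aromatic carbon degradation (0.022), phosphorus utilization (0.024) and metal resistance (0.041), and for HH minus BDGS, starch degradation (0.0070) and phosphorus utilization (-0.0024), and for SWD minus HH, phosphorus utilization (0.021). As shared-probe means it turned for SWD minus BDGS, denitrification (0.022), nitrogen fixation and ammonification (0.032), chitin and pectin degradation (-0.020), methane cycling (-0.080) and sulfur cycling (-0.010), and for HH minus BDGS, nitrate or nitrite reduction (0.042), nitrogen fixation and ammonification (0.030), cellulose and hemicellulose degradation (0.0052), lignin and aromatic carbon degradation (0.0050) and carbon fixation (0.022), and for SWD minus HH, denitrification (-0.013), nitrogen fixation and ammonification (-0.011) and starch degradation (-0.0051). After quantile normalization it turned for SWD minus BDGS, sulfur cycling (0.00057), and for HH minus BDGS, nitrogen fixation and ammonification (0.034). It also turned for SWD minus BDGS, methane cycling (-0.068), without mdh, and for HH minus BDGS, starch degradation (0.024), without BDGS arrays 2, 3 and 4. The cause was not tested.

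With each array left out in turn, families past the threshold numbered 141 to 158, 133 to 150 and 127 to 146 in the order SWD minus BDGS, HH minus BDGS and SWD minus HH, and probes 10908 to 12011, 11650 to 12505 and 6557 to 7452. The R2 of forest was 0.282 to 0.320 for the 3 forests and 0.248 to 0.286, 0.312 to 0.344 and 0.154 to 0.187 by pairs. Differences in detected probes were -801 to -605, -520 to -401 and -349 to -153, and in the Shannon index -0.0360 to -0.0275, -0.0234 to -0.0183 and -0.0155 to -0.00696. The forest differences in R2 and both comparisons with BDGS passed whichever array was left out, and SWD minus HH in detected probes and in the Shannon index passed in 0 of 18 cases.

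With the replicate number as a block, 147, 142 and 135 families and 11638, 12149 and 7206 probes passed, the pairs of forests differed in functional structure with permutation p = 0.00391 each, the smallest these permutations can give, and nifh lost its call in SWD minus BDGS and HH minus BDGS. Starch degradation in HH minus BDGS turned its direction in camera under the block (median of its members minus that of the other families 0.0078), without a call. The pairing was checked from correlations between arrays of the same number, after the forest mean was taken off: 0 of 9 were above 0.1 for SWD and BDGS, 2 of 9 for HH and BDGS and 5 of 9 for SWD and HH (medians -0.050, -0.032 and 0.16; all 27 from -0.33 to 0.43, median -0.030). Against random matchings of the numbers, a test chosen after the correlations were seen, the mean correlation had unadjusted one-sided permutation p = 0.929, 0.648 and 0.0393. Of the 27 arrays, 5 were closest to an array of their own number. The number that chance gives was not computed, so this count does not argue against pairs. The numbers were not taken as pairs, but some shared deviation between SWD and HH arrays of the same number is not excluded. These are the replicate numbers of the titles, which do not all match the numbers in the column names. A pairing by the numbers in the column names was thus not fully tested.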

Other observations

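The phyla and the fit within single forests were tests chosen only after the result was seen, while the tests of the pH hypothesis across and within forests were chosen before.

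Of 51 comparisons of 17 phyla with at least 50 probes, 25 passed an adjusted p of 0.05 in exact permutation tests, 5 for SWD and BDGS, 11 for HH and BDGS and 9 for SWD and HH. Actinobacteria held 24.5 ± 0.244% of the signal in HH, against 23.6 ± 0.337% in BDGS (adjusted p = 0.000572) and 23.4 ± 0.381% in SWD (adjusted p = 0.0003). Firmicutes held 4.04% in HH against 4.34% and 4.33%, and Bacteroidetes 1.63% against 1.79% and 1.77% (adjusted p = 0.0003 for each). Crenarchaeota were lower in HH as well (0.628%, against 0.678% in BDGS and 0.675% in SWD). Cyanobacteria were highest in BDGS, at 1.45% against 1.34% in SWD (adjusted p = 0.000572) and 1.34% in HH (adjusted p = 0.0003). Ascomycota held 4.69% in SWD against 4.43% in HH (adjusted p = 0.000968, higher in 9 of 9 arrays than the HH mean). Relative to the other shared probes these comparisons had the same sign. The sign differed for Chloroflexi in SWD minus BDGS and Verrucomicrobia in HH minus BDGS, which had passed.

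A lower share of Acidobacteria was expected in HH, where soil pH was highest. The share was 0.531% in HH against 0.563% in BDGS (difference -0.0324 percentage points, adjusted p = 0.000524, exact permutation test). In SWD it was 0.544% (SWD minus HH 0.0132 points, adjusted p = 0.124, higher than the HH mean in 6 of 9 arrays), so the expectation was met against BDGS and not settled against SWD. Within forests the share changed by -0.0127 points per pH unit (permutation p = 0.0131, 100000 resamples). The relation was negative in SWD (permutation p = 0.0359) and in HH (p = 0.0708) but positive in BDGS (p = 0.251), where the pH varied least (SD 0.185), so a fall was not seen in every forest. A fall of Acidobacteria with pH may therefore hold in these soils, and the data do not decide it.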
